A study of Mus musculus with 80 samples.

How the data were processed

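The data were RNA-seq libraries of mouse AgRP neurons: 33 of sorted NPY-GFP cells, 17 of RiboTag immunoprecipitates and, by genotype, 25 of a leptin series and 5 of a ZT5 series. Per the labels' protocols, GFP-positive cells of NPY-GFP mice were sorted by FACS from dissociated arcuate slices, RiboTag samples were immunoprecipitated, and all RNA was amplified with a SMART-seq v4 kit before Nextera XT library preparation. The protocols describe no separate collection for the leptin and ZT5 series, and the read length and the strand setting are not stated. Per the submitters' processing notes, STAR 2.5.1, featureCounts (Subread), DESeq, DESeq2 and R 3.5.1 were used with the mm10 build, with no role or order given. The deposited file holds 1 table of 23337 genes by 80 libraries, and its values are signal: normalised counts, that is gene counts divided by a size factor per library.

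In 79 libraries the low values were whole multiples of 1 step, so that reads could be recovered by dividing by it (at least 99.99% of values within 0.1 of a whole number). In the library labelled NPY-GFP ad libitum ZT2 replicate 4, 15.17% of values were whole, and it was left out of the quasi-likelihood test. The reads recovered per library ranged from 10.8 to 17.3 M in the ZT5 series, 8.16 to 27.4 in sorted NPY-GFP cells, 11.4 to 23.1 in RiboTag and 5.93 to 34 in the leptin series. Genes above 0 numbered 12672 to 15011, 13041 to 18065, 14905 to 17378 and 14277 to 16310. Mitochondrially encoded transcripts are absent from the table, so that their share could not be used as a sign of RNA quality.

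Each of the 4 experiments was fitted on its own, with all its groups, by limma 3.58.1 (limma-trend) in R 4.3.3 on log2(value + 1). Fold differences are on that scale, which understates those of low genes. Genes with a value of at least 10 in as many libraries as the smallest group were tested: 12940, 14931, 15444 and 13942 in the same order. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with 0.05 as the threshold. Groups were taken from the labels, and no library was moved or left out of the main fits. The labels number the replicates but do not say that they came from separate mice, so that p-values measure only the spread between these libraries, which may be technical. The 26 planned comparisons and 29 gene lists, the test, the filter and the rule for named genes were fixed before the data were examined. A further 4 comparisons (refed against ad libitum cells at both times and their difference, and genotype over all leptin-series libraries) were added after the data were seen. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads was run as an alternative.

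Gene lists were tested with camera, with a preset correlation of 0.01 between genes and again with an estimated one, and the core clock list also with fry. Lists with at least 3 measured genes were tested. Markers of oligodendrocytes, their precursors, microglia and endothelium passed in no comparison (lowest adjusted p = 0.201, 0.31, 0.194 and 0.0881), and erythroid markers and mitochondrially encoded transcripts had too few measured genes. Over all comparisons, 173 list calls were made with the preset correlation, of which 2 held with the estimated one, both of the leptin and JAK-STAT list. Gene positions, lengths and GC content were taken from GENCODE M21 by symbol: 20929 symbols matched directly, 1919 through an older symbol, and 489 did not match.

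By the rule fixed beforehand, the 10 genes with the largest differences in each direction past the threshold could be named in the 8 main comparisons (and, by a choice made after the data were seen, in 3 of the added ones), provided their mean log2 value was at least 5 and their symbol was not a predicted or unnamed one, and 3 in the others. In every comparison Agrp, Npy, Lepr, Socs3, Arntl, Per1, Per2, Nr1d1 and Dbp could be named, as could up to 4 called members of each list with the smallest p, or up to 2 where none was called, and Arntl stands first in the knockout comparisons. Genes outside the rule are said to have been named after their values were seen.

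The precision was tested on simulated data with the group sizes and spreads of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. limma recovered 16% and 61% of them for the ZT5 comparison, 22% and 69% for fasting at ZT14 in sorted cells, 13% and 59% for refed against ad libitum cells at ZT14, 24% and 72% for time in ad libitum cells, 4% and 27% for fasting in RiboTag at ZT2, 23% and 69% for leptin in controls at ZT14, and 29% and 84% for genotype in PBS libraries at ZT2. Of the genes left unchanged, 6, 3, 2, 9, 1, 6 and 5 were called in the same order. A list of 20 genes raised 1.5 times was found by camera in each of these comparisons, and of 50 unchanged lists at most 3 passed an unadjusted threshold of 0.05. With a trend on GC content put into the fasted libraries of the simulated ZT14 comparison, 1922 unchanged genes were called, and 3 after the GC and length correction.

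The alternatives were a pseudocount of 8, no filter, rescaling by the median of ratios, library weights, the replicate number as a block, the quasi-likelihood test, only the groups compared, and leaving out each library in turn. A correction for GC content and length, leaving out 7 doubted libraries, a term for fasted libraries with low Lars2, and ZT5 control 2 alone in the ZT5 minus PBS difference were chosen after the data were seen. The doubted libraries were NPY-GFP ad libitum ZT2 replicate 4, fasted ZT14 replicates 3 and 4 and fasted ZT2 replicate 6 (Gfap above 500), RiboTag fasted ZT2 replicate 3 (a mean correlation below 0.8 with its group), and the libraries labelled ZT5 control 1 and knockout 3. Comparisons that share libraries were set against 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No column of the table was left out.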

Results

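The series followed AgRP neurons of the mouse arcuate nucleus, cells that drive feeding and that also make the peptide NPY, across feeding states, times of day, leptin injection and loss of the clock gene Arntl (also called Bmal1). RNA was sequenced in 80 libraries from 20 groups of 2 to 8 libraries. NPY-GFP cells sorted from arcuate slices gave 33 libraries: 6 from ad libitum fed mice at ZT2 (2 hours after lights on) and 3 at ZT14 (2 hours after lights off), 7 and 8 after a fast of 24 hours, and 5 and 4 after 1 hour of refeeding. RiboTag immunoprecipitates, which hold RNA bound to tagged ribosomes of AgRP-Cre cells, gave 17: 3 and 4 from ad libitum fed mice at ZT2 and ZT14, and 5 and 5 from fasted mice. A leptin series of 25 libraries compared floxed controls with AgRP-Cre knockouts, after leptin or PBS, at ZT2 and ZT14, with 3 libraries per group except for 4 control PBS libraries at ZT2. A series at ZT5 held 3 knockout and 2 control libraries. The reads recovered per library ranged from 5.93 to 34 M (median 14.3 M).

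Values are deposited normalised counts, given as mean ± SD over libraries. Differences are log2 differences ± standard error, with p-values from limma adjusted over all genes tested. Set tests are from camera. Positions are on mm10: Agrp lies on chromosome 8 (105566698 to 105637393), Npy on chromosome 6 (49822710 to 49829507), Lepr on chromosome 4 (101717404 to 101815352), Vgf on chromosome 5 (137026392 to 137033351), Arntl on chromosome 7 (113207465 to 113314126), Per2 on chromosome 1 (91415982 to 91459324) and Socs3 on chromosome 11 (117966079 to 117970047).

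All 25 fasted libraries, from sorted cells and RiboTag alike, and all 5 ZT5 libraries shared a profile that the other 50 libraries lacked. Cebpb, a transcription factor gene, lay between 42.5 and 1560 in the fasted libraries and between 433 and 630 at ZT5, against 0 to 17.1 in the others. Alyref, which acts in mRNA export, lay between 545 and 2760, between 1270 and 2170, and between 12.3 and 81.8. The ribosomal RNA precursor Rn45s was lower by median (8300 and 3110 against 210000), with ranges of 1730 to 148000, 1580 to 4010 and 50800 to 963000 that overlapped through RiboTag libraries. The labels do not call the ZT5 mice fasted. The difference between the ZT5 controls and the PBS controls of the leptin series at ZT2 (both floxed, without Cre by label, and not labelled fasted) is therefore given at least once for each gene group of the feeding comparisons below as the ZT5 minus PBS median. Of the 5593 genes called between fasted and ad libitum NPY-GFP cells at ZT2, 73% had a ZT5 minus PBS difference of the same sign, as had 73.3% of the 2758 called at ZT14. One of the 2 ZT5 controls, control 1, had Hsd11b2 at 4628.3, against its label. With control 2 alone the shares were 71% and 71.9%.

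**Figure D1:**
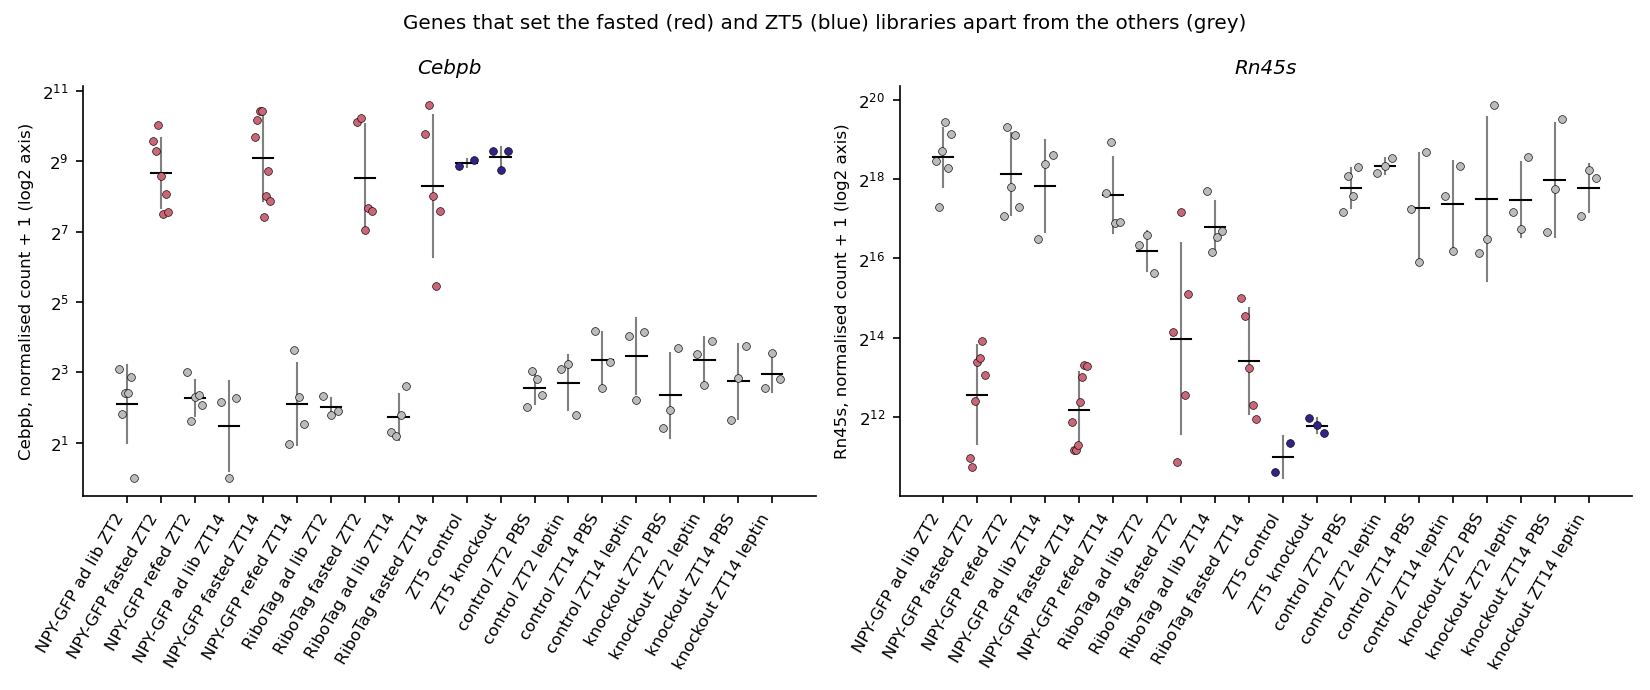
Cebpb and Rn45s in all 80 libraries (points; black line, mean; grey bar, 1 SD either side, on the log2 scale), with Cebpb medians of 381 in fasted, 525 in ZT5 and 4.21 in all other libraries.

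The first question was how fasting changes the RNA of AgRP neurons. In sorted NPY-GFP cells at ZT2 (7 fasted, 6 ad libitum libraries), Agrp rose by 1.58 ± 0.332 (adjusted p = 0.0003), from 45530 ± 13980 to 140600 ± 56820, with all 7 fasted libraries above all 6 others. Npy rose by 1.16 ± 0.421 (adjusted p = 0.0279), from 218800 ± 91620 to 511300 ± 249100, with 4 of the 7 above all others. This call was lost in 7 of 21 alternatives. These were no filter (adjusted p = 0.0684) and leaving out ad libitum ZT2 replicates 1, 2 or 6 (0.0581, 0.0553 and 0.0625) or fasted ZT2 replicates 1, 3 or 4 (0.0635, 0.0626 and 0.0501). Lepr, the leptin receptor, rose by 1.14 ± 0.365 (adjusted p = 0.0137), with 2 of the 7 above all others. The quasi-likelihood test did not call it (adjusted p = 0.0546). Vgf, the gene of a neuropeptide precursor, rose from 62.92 ± 40.49 to 6098 ± 4164 (6.53 ± 0.417, adjusted p = 1.23e-13). Nts, the neurotensin gene, rose by 7.66 ± 0.774, the cell cycle inhibitor gene Cdkn1a by 6.09 ± 0.572 and the metallothionein gene Mt2 by 6.47 ± 0.621, each in 7 of 7 libraries. Cebpb rose by 6.56 ± 0.59. ZT5 minus PBS differences were 6.40 for it and -1.33, -1.98, -3.93 and -1.65 for Vgf, Nts, Cdkn1a and Mt2. Agrp, Npy, Lepr, Vgf, Nts and Cdkn1a were also called in refed cells. Such genes (98.3% or more, Vgf too) differed alike between PBS and ad libitum libraries. Sstr1, a somatostatin receptor gene, fell by 5.05 ± 0.537 and Rn45s by 5.98 ± 0.519 (ZT5 minus PBS, 0.26 and -6.79).

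Of 19 core clock genes, 3 rose and 8 fell with fasting at ZT2 (3 and 10 adjusted over the list alone), and the set did not pass (adjusted p = 0.127, and adjusted p = 0.462 with an estimated correlation). Per3 fell from 1051 ± 438.5 to 75.59 ± 63.22 (-4.01 ± 0.395, adjusted p = 1.78e-09), and Nr1d2 and Nr1d1, which encode the REV-ERB repressors, fell by 2.35 ± 0.4 and 1.73 ± 0.321. Nfil3 rose by 3.46 ± 0.334, Cry1 by 3.42 ± 0.344 and Arntl by 0.79 ± 0.257 (adjusted p = 0.0148). Per2 was 76.85 ± 36.28 in fasted and 69.55 ± 39.94 in ad libitum cells (adjusted p = 0.777).

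Of 17 immediate early genes, which respond to neuronal activity, 9 rose at ZT2 and 0 fell (10 adjusted over the list alone), among them Fos (1.21 ± 0.271) and Egr1 (1.28 ± 0.329), with adjusted p = 0.0241 for the set, adjusted p = 0.462 with an estimated correlation and a ZT5 minus PBS median of -0.594. Of 14 glucocorticoid response genes, 9 rose (10 adjusted over the list alone), among them Fkbp5 (2.16 ± 0.317), with adjusted p = 0.000471, adjusted p = 0.381 with an estimated correlation and a ZT5 minus PBS median of -1.26. Of 24 genes of protein folding in the endoplasmic reticulum, 17 rose and 2 fell (18 and 3 adjusted over the list alone). The chaperone gene Hspa5 went from 10950 ± 1664 to 39650 ± 17110 (1.77 ± 0.256), and the set had adjusted p = 9.42e-05, adjusted p = 0.381 with an estimated correlation and a ZT5 minus PBS median of 0.042. Of 37 genes of protein translocation and secretion, 16 rose and 2 fell (16 and 2 adjusted over the list alone), with adjusted p = 0.000471, adjusted p = 0.462 with an estimated correlation and a ZT5 minus PBS median of -0.00786.

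Of 58 cytosolic ribosomal protein genes, 42 fell and 0 rose at ZT2 (45 and 0 adjusted over the list alone). Rpsa fell by 1.65 ± 0.209 and Rps12 by 2.01 ± 0.29, each below all ad libitum libraries in 7 of 7, and the set had adjusted p = 9.97e-12, adjusted p = 0.462 with an estimated correlation and a ZT5 minus PBS median of 0.168. Of 30 potassium channel genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone), with adjusted p = 0.00141, adjusted p = 0.381 with an estimated correlation and a ZT5 minus PBS median of -0.899. Of 15 GABA receptor genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone), with adjusted p = 0.0248, adjusted p = 0.427 with an estimated correlation and a ZT5 minus PBS median of -1.12. Of 18 cholesterol synthesis genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone), among them Hmgcs1 (-1.41 ± 0.266), with adjusted p = 0.0248, adjusted p = 0.462 with an estimated correlation and a ZT5 minus PBS median of -0.69.

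Of 20 autophagy genes, 6 rose at ZT2 (6 adjusted over the list alone), with adjusted p = 0.0241, adjusted p = 0.381 with an estimated correlation and a ZT5 minus PBS median of 0.203. Of 18 genes of fatty acid oxidation and ketone use, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with adjusted p = 0.0364, adjusted p = 0.427 with an estimated correlation and a ZT5 minus PBS median of 0.126. Of 6 markers of POMC neurons, the neighbouring cells that curb feeding, 4 rose (4 adjusted over the list alone), with adjusted p = 0.0257, adjusted p = 0.381 with an estimated correlation and a ZT5 minus PBS median of -0.123. Pomc itself rose by 2.21 ± 0.775 (adjusted p = 0.0231; 6077 ± 11400 against 309.3 ± 105.6). That call was lost in 4 of 21 alternatives (1.41 to 4.34): with library weights (adjusted p = 0.055), without doubted libraries (0.0728) and without fasted ZT2 replicate 3 (0.0801) or 6 (0.0671). Of 11 markers of other hypothalamic neurons, 6 rose (6 adjusted over the list alone), Gal by 2.45 ± 0.393 and Sst by 1.40 ± 0.349, with adjusted p = 0.0248, adjusted p = 0.381 with an estimated correlation and a ZT5 minus PBS median of 0. Of 11 astrocyte markers, 3 rose (3 adjusted over the list alone), and the set did not pass (adjusted p = 0.0535, and adjusted p = 0.633 with an estimated correlation). These were Aldh1l1 (4.39 ± 0.542, above all others in 7 of 7 libraries), Gja1 (4.28 ± 1.36, 3 of 7) and Agt (4.62 ± 1.47, 4 of 7), the last not called without doubted libraries (adjusted p = 0.0711). Cd68 rose by 5.10 ± 0.605 (7 of 7) and the endothelial marker Ly6c1 by 2.94 ± 0.737 (5 of 7). The fasting difference of all genes ran with transcript length (Spearman rho -0.346 at ZT2 and -0.233 at ZT14, and -0.486 and -0.298 in RiboTag libraries). With the GC and length correction, the sets of immediate early (adjusted p = 0.123), potassium channel (0.108), GABA receptor (0.655), autophagy (0.0621) and fatty acid oxidation genes (0.183) were lost at ZT2, and the GABA receptor gene Gabrg3 went from -1.04 ± 0.269 to 0.21. In all, 2726 genes rose and 2867 fell among 14931 tested, and the quasi-likelihood test called 5002.

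At ZT14 (8 fasted, 3 ad libitum libraries), Lepr rose from 402.1 ± 148.3 to 1122 ± 441.9 (1.45 ± 0.445, adjusted p = 0.0202) and Vgf by 5.65 ± 0.507, each with 8 of 8 fasted libraries above all others. Lepr was not called without ad libitum ZT14 replicate 1 (adjusted p = 0.147) or 3 (0.064). Agrp was 125100 ± 55620 in fasted and 58500 ± 24350 in ad libitum cells (1.01 ± 0.404, adjusted p = 0.0784). Npy was 453900 ± 238400 and 227800 ± 103100 (0.86 ± 0.512, adjusted p = 0.254). Mt2 rose by 5.73 ± 0.756, Cdkn1a by 6.19 ± 0.696 and Nfil3 by 2.77 ± 0.406, while Per3 fell by 1.74 ± 0.48 (adjusted p = 0.01, and 0.0558 without ad libitum ZT14 replicate 1). Immediate early genes rose in 5 of 17 cases (7 adjusted over the list alone), among them Egr1 (1.89 ± 0.4), with adjusted p = 0.000386 and adjusted p = 0.589 with an estimated correlation. Glucocorticoid response genes rose in 7 of 14 cases (7 adjusted over the list alone), with adjusted p = 6.97e-06 and adjusted p = 0.589 with an estimated correlation. Ribosomal protein genes fell in 24 of 58 cases (35 adjusted over the list alone), with adjusted p = 3.28e-12 and adjusted p = 0.668 with an estimated correlation.

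Protein folding genes rose in 9 of 24 cases at ZT14 and 1 fell (11 and 1 adjusted over the list alone), with adjusted p = 0.0323 and adjusted p = 0.668 with an estimated correlation. Potassium channel genes fell in 7 of 30 cases and 1 rose (7 and 1 adjusted over the list alone), with adjusted p = 0.00938 and adjusted p = 0.589 with an estimated correlation. Of the secretory pathway genes, 8 of 37 rose and 1 fell (10 and 1 adjusted over the list alone), with adjusted p = 0.0464 and adjusted p = 0.729 with an estimated correlation. With the GC and length correction the folding (adjusted p = 0.125), potassium channel (0.206) and secretory sets (0.125) were lost. Of 11 astrocyte markers, 5 rose (8 adjusted over the list alone), Aldh1l1 by 3.05 ± 0.66, with adjusted p = 0.000772, adjusted p = 0.63 with an estimated correlation and a ZT5 minus PBS median of -1.94. Of the genes tested, 1442 rose and 1316 fell, and the quasi-likelihood test called 2624. The count was 1244 without ad libitum ZT14 replicate 2 and 1697 without replicate 3. The difference between both fasting effects was tested directly: limma called 0 genes at adjusted p under 0.05 (647 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test), with -0.57 ± 0.523 for Agrp (adjusted p = 0.999), -0.31 ± 0.662 for Npy (adjusted p = 0.999) and 0.32 ± 0.575 for Lepr (adjusted p = 0.999).

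**Figure D2:**
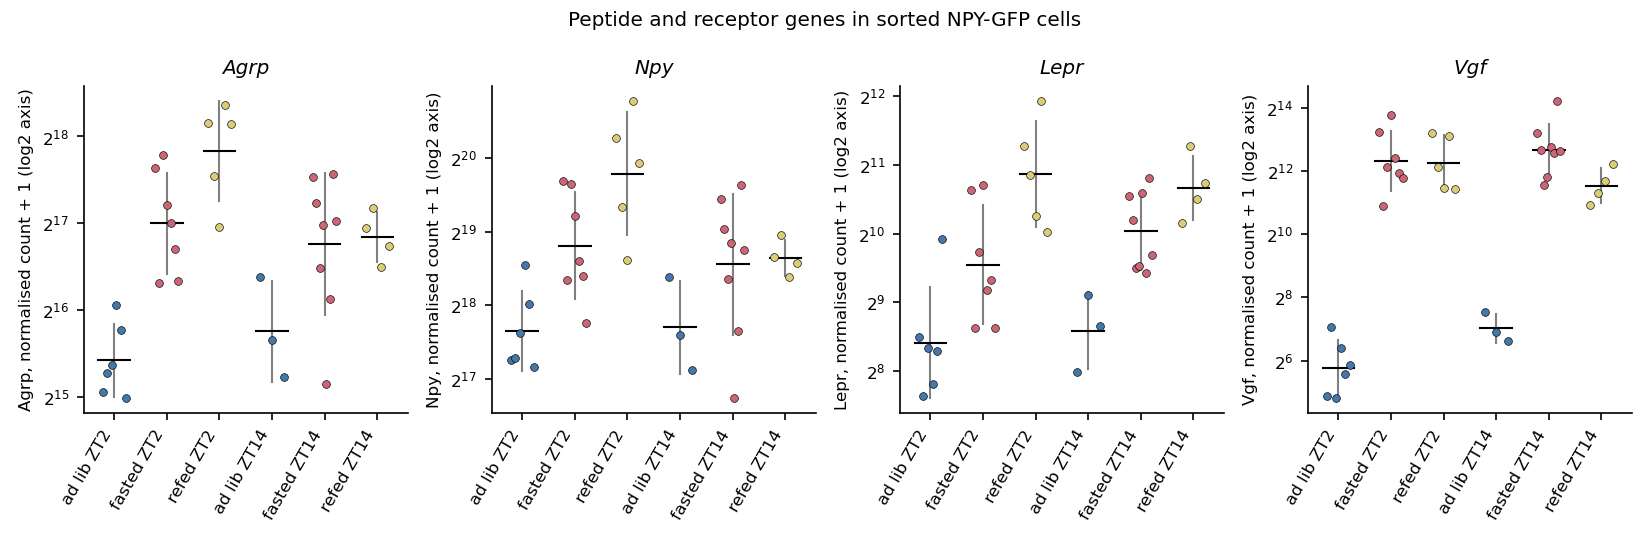
Agrp, Npy, Lepr and Vgf in the 33 libraries of sorted NPY-GFP cells (points; black line, mean; grey bar, 1 SD either side, on the log2 scale). At ZT2, mean Agrp was 45530 in ad libitum, 140600 in fasted and 247500 in refed cells.

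The next question was what 1 hour of refeeding did. At ZT2 (5 refed, 7 fasted libraries), Egr1 fell by 1.79 ± 0.346, below all fasted libraries in 4 of 5. Of the immediate early genes, 7 of 17 fell (8 adjusted over the list alone), with adjusted p = 0.00995 and adjusted p = 0.818 with an estimated correlation. Ribosomal protein genes rose in 29 of 58 cases (34 adjusted over the list alone), Rpsa from 2224 ± 242.3 to 5288 ± 907.7 (1.24 ± 0.22), with adjusted p = 9.23e-12 and adjusted p = 0.818 with an estimated correlation. The insulin receptor gene Insr rose by 1.89 ± 0.288 in 5 of 5 libraries, with a ZT5 minus PBS difference of -2.74. Lepr rose by 1.32 ± 0.385 (adjusted p = 0.0114) and Socs3, a feedback inhibitor of leptin signalling, fell by 2.03 ± 0.609 (adjusted p = 0.0144). Neither was called without refed ZT2 replicate 4 (adjusted p = 0.0631 and 0.0976) or with the GC and length correction (0.121 and 0.0835). Agrp was 247500 ± 85850 in refed cells (0.83 ± 0.349 above fasted, adjusted p = 0.0841) and Npy did not pass either (adjusted p = 0.112).

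Of 14 genes that mark AgRP neurons, 4 rose and 1 fell with refeeding at ZT2 (6 and 1 adjusted over the list alone), with adjusted p = 0.0252, adjusted p = 0.818 with an estimated correlation and a ZT5 minus PBS median of -0.719. Secretory pathway genes rose in 8 of 37 cases and 1 fell (8 and 1 adjusted over the list alone), with adjusted p = 0.0426 and adjusted p = 0.818 with an estimated correlation. Nfil3 fell by 2.60 ± 0.351. Of 11 astrocyte markers, 4 fell (5 adjusted over the list alone), Gja1 by 6.21 ± 1.43, and the set did not pass (adjusted p = 0.0748, and adjusted p = 0.818 with an estimated correlation). Cebpb fell by 6.39 ± 0.621 and Rn45s rose by 5.55 ± 0.547, with ZT5 minus PBS differences of the opposite sign (6.40 and -6.79). In all, 1609 genes rose and 1653 fell (quasi-likelihood, 3227 called), and 12.3% of them had a ZT5 minus PBS difference of the same sign (15.5% with ZT5 control 2 alone).

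At ZT14 (4 refed, 8 fasted libraries), Egr1 fell by 1.42 ± 0.362, below all fasted libraries in 4 of 4 (not called without refed ZT14 replicate 4, adjusted p = 0.06). Of the immediate early genes, 4 of 17 fell (5 adjusted over the list alone), with adjusted p = 0.00427 and adjusted p = 0.717 with an estimated correlation. Ribosomal protein genes rose in 13 of 58 cases (21 adjusted over the list alone), with adjusted p = 4.01e-09 and adjusted p = 0.717 with an estimated correlation. Nfil3 fell by 3.12 ± 0.367. Of 11 astrocyte markers, 1 fell (1 adjusted over the list alone; median -2.82), with adjusted p = 0.0194 and adjusted p = 0.717 with an estimated correlation. Agrp (0.07 ± 0.365) and Npy (0.09 ± 0.463) did not pass. Of the genes tested, 950 rose and 791 fell (quasi-likelihood, 1676 called), and the count was 1138 without refed ZT14 replicate 2.

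Refed and ad libitum cells were compared after the first results were seen, since neither group has the profile of the fasted libraries. At ZT2 (5 refed, 6 ad libitum), Agrp was higher by 2.41 ± 0.361 (adjusted p = 2.14e-05), Npy by 2.14 ± 0.458 (adjusted p = 0.00149) and Lepr by 2.46 ± 0.398 (adjusted p = 6.98e-05). Vgf was higher by 6.49 ± 0.454, Nts by 8.76 ± 0.842 and Cdkn1a by 7.55 ± 0.622, and in 5 of 5 refed libraries Vgf lay above all others. In the PBS controls of the leptin series, which are not labelled fasted, Vgf was 3578 ± 308.5 at ZT2 and 1970 ± 490.4 at ZT14. Genes called alike in fasted and in refed cells were set against PBS controls minus ad libitum libraries not used for the calls. At ZT2, 99% of 795 and 98.3% of 647 genes (odd and even libraries) lay on the side of the fasting call, and in RiboTag ad libitum libraries minus the same ones 75.3% and 68%. At ZT14, with 1 ad libitum library held out in turn, all 40, 31 and 20 genes did so. In RiboTag fasting, 73.1% of the genes called alike at ZT2 (median 0.441) and 85.2% at ZT14 (median 1.12) lay on that side. Per3 (-4.17 ± 0.43), Nr1d2 (-2.92 ± 0.435) and Nr1d1 (-2.42 ± 0.349) were lower, and of 19 core clock genes 8 were lower and 2 higher (9 and 3 adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.294 with an estimated correlation), with a ZT5 minus PBS median of -0.318. Secretory pathway genes were higher in 21 of 37 cases (25 adjusted over the list alone), with adjusted p = 1.59e-14 and adjusted p = 0.172 with an estimated correlation. Protein folding genes were higher in 16 of 24 cases (18 adjusted over the list alone), Hspa5 by 1.85 ± 0.279, with adjusted p = 2.03e-11 and adjusted p = 0.141 with an estimated correlation.

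Glucocorticoid response genes were higher in refed cells at ZT2 in 7 of 14 cases (8 adjusted over the list alone), with adjusted p = 5.89e-05 and adjusted p = 0.31 with an estimated correlation. Of 17 genes of neuropeptide processing, 8 were higher and 3 lower (9 and 3 adjusted over the list alone), with adjusted p = 0.00847, adjusted p = 0.387 with an estimated correlation and a ZT5 minus PBS median of -0.297. Cholesterol synthesis genes were lower in 6 of 18 cases and 1 was higher (8 and 1 adjusted over the list alone), with adjusted p = 0.023 and adjusted p = 0.65 with an estimated correlation. Of 11 astrocyte markers, 2 were higher (2 higher and 1 lower adjusted over the list alone), and the set did not pass (adjusted p = 0.888, and adjusted p = 0.954 with an estimated correlation). These were Aldh1l1 (4.47 ± 0.59, above all others in 5 of 5 libraries) and Agt (5.31 ± 1.6, 2 of 5), the latter lost by the quasi-likelihood test (adjusted p = 0.103) and without refed ZT2 replicate 4 (0.088). Cd68 was higher by 5.41 ± 0.659 (5 of 5) and the endothelial marker Ly6c1 by 2.62 ± 0.802 (4 of 5), the latter lost without ad libitum ZT2 replicate 3 (0.0533) or refed ZT2 replicates 1, 2 or 5 (0.0626, 0.0694 and 0.0506). Of the 2648 genes called, 1346 were higher, and 41.6% had a ZT5 minus PBS difference of the same sign (42.9% with ZT5 control 2 alone). The median difference of all genes was -0.137, and 50.8% of the calls were higher against 68.4% of the 1770 calls by the quasi-likelihood test. Without refed ZT2 replicate 4, 1439 genes were called.

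At ZT14 (4 refed, 3 ad libitum), 54 genes were higher and 2 lower. The 56 calls became 362 with only the groups compared, 737 with library weights and 105 with the GC and length correction. Vgf was higher by 4.51 ± 0.572 in 4 of 4 libraries. Lepr was higher by 2.08 ± 0.502 (adjusted p = 0.0524) and Agrp by 1.08 ± 0.456 (adjusted p = 0.598), neither past the threshold. Of the glucocorticoid response genes, 3 of 14 were higher (3 adjusted over the list alone; adjusted p = 4.06e-06, and adjusted p = 0.511 with an estimated correlation). The count of genes was 32 without ad libitum ZT14 replicate 2 and 21 without replicate 3. The test of the difference between ZT2 and ZT14 called 0 genes in limma (684 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test), with -1.33 ± 0.581 for Agrp (adjusted p = 1), -1.20 ± 0.737 for Npy (adjusted p = 1) and a median of all genes of 0.105 after rescaling. It called 1 without refed ZT2 replicate 1 and 2 without replicate 4.

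The overlaps between these comparisons were counted per direction. At ZT2, 2257 genes were called with fasting and in the opposite direction with refeeding, 970 of them higher and 1287 lower with fasting, against 302 and 309 for independent lists. These comparisons share the fasted libraries. Unchanged groups, with few calls to share, shared at most 0 genes in 20 simulations, with mean correlation -0.44 (observed -0.611) and covariance -0.129 (-0.807). With the fasted libraries split between both comparisons, 1232 and 1461 genes were shared. At ZT14 the count was 1319 (615 and 704, against 76.4 and 83.7), with a covariance of -0.884 against -0.115 simulated, and 834 and 782 with the split (820 without ad libitum ZT14 replicate 2). Genes called alike in fasted and in refed cells against ad libitum cells numbered 1647 at ZT2 (1020 higher and 627 lower, against 246 and 250), with a correlation of 0.541 against 0.493 simulated, a covariance of 0.671 against 0.149 simulated, 577 and 680 with the ad libitum libraries split, and 1059 without refed ZT2 replicate 4. At ZT14 there were 54 (53 and 1, against 5.22 and 0.176; at most 1 in the simulations), with a correlation of 0.613, below the 0.645 simulated, a covariance of 0.557 against 0.302 simulated, 31 without ad libitum ZT14 replicate 2 and 20 without replicate 3. The 3 ad libitum libraries were too few to split, so part of this excess may come from the shared libraries.

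RiboTag libraries addressed the effect of fasting on RNA bound to ribosomes. At ZT2 (5 fasted, 3 ad libitum), Agrp rose by 3.49 ± 0.992 (adjusted p = 0.0385), with 5 of 5 libraries above all others, from 12540 ± 7961 to 353700 ± 635400, a mean that fasted replicate 5 (1488900) dominated. The Agrp call was lost in 8 of 16 alternatives (1.93 to 4.96): without the filter (adjusted p = 0.0559), with the replicate block (0.0505), with the GC and length correction (0.213), without ad libitum ZT2 replicates 1, 2 or 3 (0.177, 0.122 and 0.0576) and without fasted ZT2 replicates 4 or 5 (0.0577 and 0.053). Npy was higher by 2.96 ± 0.921 (adjusted p = 0.0565), short of the threshold. Vgf rose from 578.5 ± 251.2 to 16770 ± 10720 (4.45 ± 0.79) and Sst rose by 3.23 ± 0.651. More markers of other cells were called: Pomc rose by 3.32 ± 0.907 (above all others in 4 of 5 libraries), Gal by 3.14 ± 0.805 and Cartpt by 2.17 ± 0.614 (5 of 5 each), and the oligodendrocyte precursor marker Cspg4 fell by 3.20 ± 0.837 (4 of 5). Of 16 alternatives Pomc was lost in 5, Gal in 3, Cartpt in 7 and Cspg4 in 3. These were the GC and length correction (adjusted p = 0.138 for Pomc, 0.0566 for Cspg4), no filter (Cartpt 0.051), leaving out doubted libraries (Cartpt 0.0608), leaving out ad libitum ZT2 replicates 1 (Cartpt 0.08, Cspg4 0.153), 2 (Pomc 0.165, Gal 0.139, Cartpt 0.182, Cspg4 0.118) or 3 (Pomc 0.101, Gal 0.0842, Cartpt 0.0794) and leaving out fasted ZT2 replicates 2 (Pomc 0.0694), 3 (Cartpt 0.0608), 4 (Pomc 0.0619) or 5 (Gal 0.0526, Cartpt 0.0777). Among the largest falls were Notch2 (-4.22 ± 0.872) and Mrc2 (-3.73 ± 0.79), lost without ad libitum ZT2 replicate 2 (0.0657 and 0.0773). Insr fell by 2.84 ± 0.513, with a ZT5 minus PBS difference of -2.74. Nfil3 rose by 3.27 ± 0.555. The astrocyte marker Gfap lay between 2240.8 and 25760 in all 17 RiboTag libraries.

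Of 58 ribosomal protein genes in RiboTag libraries at ZT2, 1 rose (0 adjusted over the list alone; median 1.4), with adjusted p = 1.65e-10, adjusted p = 0.918 with an estimated correlation and a ZT5 minus PBS median of 0.168. This was Rpl30 (2.28 ± 0.658, adjusted p = 0.041), lost in 9 of 16 alternatives: no filter (adjusted p = 0.0665), without doubted libraries (0.0723) and without ad libitum ZT2 replicates 1, 2 or 3 (0.13, 0.154 and 0.085) or fasted ZT2 replicates 2, 3, 4 or 5 (0.0501, 0.0723, 0.0562 and 0.0904). Of 74 nuclear genes of oxidative phosphorylation, 0 rose (0 adjusted over the list alone; median 1.77), with adjusted p = 1.55e-11, adjusted p = 0.918 with an estimated correlation and a ZT5 minus PBS median of 0.839. Secretory pathway genes rose in 6 of 37 cases (8 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.918 with an estimated correlation), glucocorticoid response genes in 2 of 14 (2 adjusted over the list alone; adjusted p = 0.00697, and adjusted p = 0.918 with an estimated correlation; ZT5 minus PBS median -1.26). Neuropeptide processing genes rose in 3 of 17 cases (3 adjusted over the list alone; adjusted p = 0.0117, and adjusted p = 0.918 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 18 cases (5 adjusted over the list alone), with adjusted p = 0.00697 and adjusted p = 0.918 with an estimated correlation.

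Of all genes at ZT2 in RiboTag libraries, 630 rose and 589 fell. The median difference of all genes was -0.185, and the share of higher genes among the calls was 51.7%, against 65.1% after rescaling and 68.8% of the 1467 calls by the quasi-likelihood test. The count moved to 480, 439 and 712 without ad libitum ZT2 replicates 1, 2 and 3, and to 2252 without fasted ZT2 replicate 1. Of the genes called, 85.8% had a ZT5 minus PBS difference of the same sign (82.3% with ZT5 control 2 alone), and 815 were called in the same direction in sorted cells at ZT2 (433 higher and 382 lower, against 118 and 114 for independent lists), 18 in the opposite one. The shared count was 379, 341 and 453 without ad libitum ZT2 replicates 1, 2 and 3.

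At ZT14 (5 fasted, 4 ad libitum), Vgf rose in RiboTag libraries from 578.6 ± 202.2 to 9816 ± 6393 (3.81 ± 0.726) and Fkbp5 by 2.59 ± 0.528. Each lay above all ad libitum libraries in 5 of 5. Per3 fell by 1.97 ± 0.469 (not called without ad libitum ZT14 replicates 1 or 2, adjusted p = 0.0599 and 0.0524) and Insr by 2.17 ± 0.471. Agrp (26450 ± 17970 against 13280 ± 1604, adjusted p = 0.828) and Npy (adjusted p = 0.782) did not pass. Glucocorticoid response genes rose in 4 of 14 cases (4 adjusted over the list alone), with adjusted p = 0.00246 and adjusted p = 0.98 with an estimated correlation. In all, 641 genes rose and 176 fell (quasi-likelihood, 811). The median of all genes was -0.158, and 78.5% of the calls were higher, against 86.3% after rescaling and 88.3% by the quasi-likelihood test. Of the calls, 78.9% had a ZT5 minus PBS difference of the same sign (74.9% with ZT5 control 2 alone), and 456 were shared with sorted cells at ZT14 (372 higher and 84 lower, against 63.3 and 15.9), 3 in the opposite direction. The test of the difference between ZT2 and ZT14 called 0 genes in limma (252 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test), with -2.98 ± 1.35 for Agrp (adjusted p = 1).

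Time of day was the next question. In fasted NPY-GFP cells, Arntl was lower at ZT14 than at ZT2 (-1.88 ± 0.239, adjusted p = 5.59e-05; 251.9 ± 91.54 against 877.4 ± 205.6), in 8 of 8 libraries below all 7 others. Nr1d2 was higher by 2.71 ± 0.372 (adjusted p = 0.000144) and Per2 by 2.21 ± 0.385 (adjusted p = 0.00451), each in 8 of 8 libraries. Per3 was higher by 1.74 ± 0.367 (adjusted p = 0.0269; quasi-likelihood, adjusted p = 0.0654). This call was lost in 8 of 24 alternatives, the others being the replicate block (0.052) and leaving out fasted ZT14 replicates 3, 4 or 6 (0.0517, 0.0512 and 0.0511) or fasted ZT2 replicates 1, 3 or 5 (0.0606, 0.0756 and 0.0596). Of 19 core clock genes, 3 were higher and 1 lower (7 and 3 adjusted over the list alone; adjusted p = 0.000379, and adjusted p = 0.0753 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.17 (0 of 74 called, 0 adjusted over the list alone; adjusted p = 0.000379, and adjusted p = 0.715 with an estimated correlation) and ribosomal protein genes -0.178 (0 of 58 called, 0 adjusted over the list alone; adjusted p = 0.00249, and adjusted p = 0.715 with an estimated correlation), and with library weights both sets were higher instead (adjusted p = 0.0039 and 0.000197). Agrp (-0.24, adjusted p = 0.885) and Npy (-0.25, adjusted p = 0.903) did not pass. In all, 34 genes were higher and 8 lower at ZT14 (quasi-likelihood, 26). Of 100 splits of these libraries, 7 called at least as many, the real one included. The 42 calls became 9 with the replicate block, 10 with only the groups compared, 26 without the filter, 75 with the GC and length correction, 72 with a term for low-Lars2 libraries and 301 with library weights. They became 25, 24 and 22 without fasted ZT14 replicates 2, 6 and 8, and 24, 18, 67 and 25 without fasted ZT2 replicates 1, 3, 4 and 6.

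In refed cells (4 against 5), 4 genes were called, named after their values were seen: Nr1d2 (2.84 ± 0.482, adjusted p = 0.0107), Gm129 (5.31 ± 0.911, adjusted p = 0.0107), a clock repressor now called Ciart, Per3 (2.48 ± 0.476, adjusted p = 0.0461) and, lower, Leo1 (-0.92 ± 0.181, adjusted p = 0.0485). Of these, Gm129, Per3 and Leo1 separated the times in 4 of 4 libraries and Nr1d2 in 3. Nr1d2 and Gm129 were lost by the quasi-likelihood test (adjusted p = 0.368 and 0.135), without refed ZT14 replicates 1 (0.0855 and 0.0909), 2 (0.0784 and 0.0633) or 3 (0.0804 and 0.0811) and without refed ZT2 replicate 2 (0.0751 for both). Per3 was lost in 8 of 17 alternatives (up to 0.372) and Leo1 in 12 of 17 (up to 0.281), both without refed ZT14 replicates 1, 2 or 3 or refed ZT2 replicates 2, 4 or 5, and Leo1 without refed ZT2 replicate 3 (0.063). The quasi-likelihood test called 0 (1138 at an unadjusted p under 0.05 in limma). The count was 0, 1 and 0 without refed ZT14 replicates 1, 2 and 3, and 43, 0, 7 and 2 without refed ZT2 replicates 1, 2, 3 and 4. In refed cells, cholesterol synthesis genes had a median of 0.76 (0 of 18 called, 7 adjusted over the list alone; adjusted p = 2.05e-10, and adjusted p = 0.0943 with an estimated correlation). In ad libitum cells (3 against 6), limma called 0 genes (413 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test). There Per2 was 296.2 ± 82.58 at ZT14 and 69.55 ± 39.94 at ZT2 (2.21, adjusted p = 0.429), with 3 of 3 libraries above all others. In RiboTag libraries limma called 0 genes between the times in ad libitum (92 at an unadjusted p under 0.05) and in fasted mice (1381), and the quasi-likelihood test 0 in both. The count was 1 without RiboTag ad libitum ZT2 replicate 2 and 3 without RiboTag fasted ZT2 replicate 1. In fasted RiboTag libraries the ribosomal protein genes had a median of -1.54 (0 of 58 called, 40 lower adjusted over the list alone; adjusted p = 4.47e-31, and adjusted p = 0.587 with an estimated correlation).

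**Figure D3:**
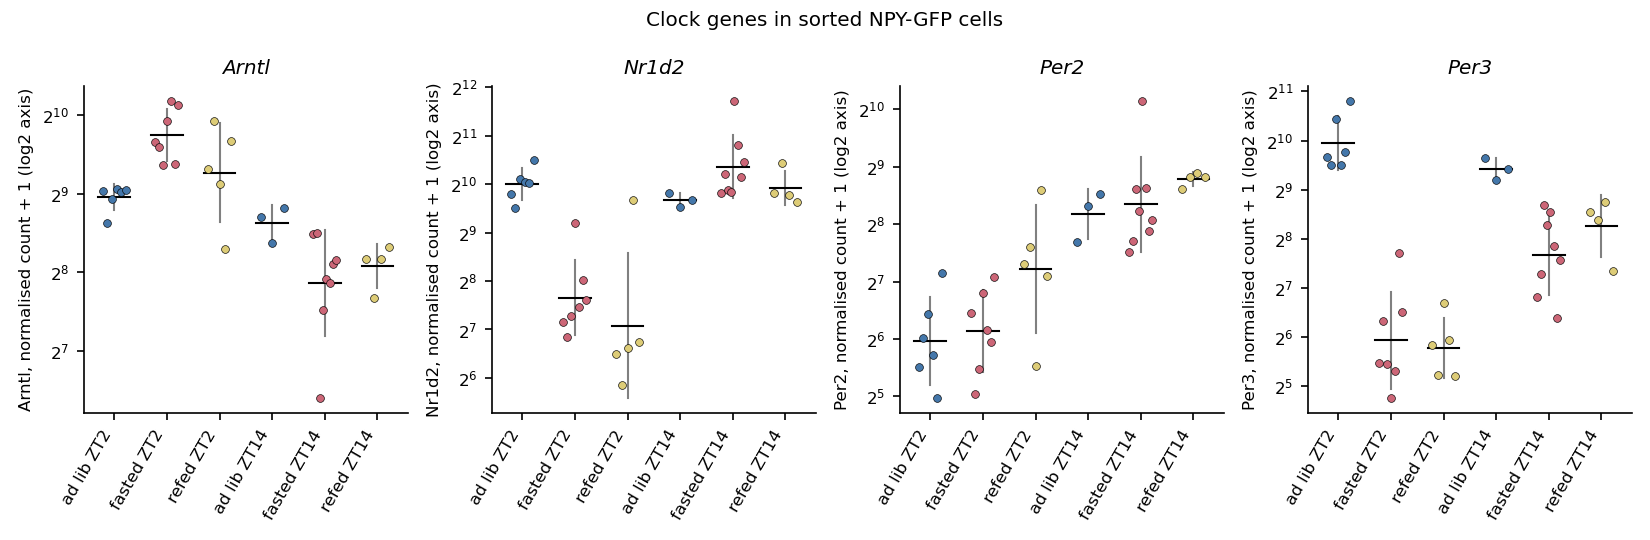
Arntl, Nr1d2, Per2 and Per3 in the 33 libraries of sorted NPY-GFP cells (points; black line, mean; grey bar, 1 SD either side, on the log2 scale). In fasted cells, mean Arntl was 877.4 at ZT2 and 251.9 at ZT14, and mean Nr1d2 was 231.9 and 1454.

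The leptin series asked what leptin changes in controls and in knockouts. In controls at ZT2 (3 leptin, 4 PBS), 3 genes rose, named after their values were seen: Steap4, a metalloreductase gene (7.80 ± 1, adjusted p = 0.000828; 285.1 ± 127.5 against 0.2564 ± 0.5128), Rnf122 (2.83 ± 0.431, adjusted p = 0.00679) and Arid5a (adjusted p = 0.0293), each in 3 of 3 libraries. Rnf122 was not called without leptin ZT2 replicates 2 or 3 (adjusted p = 0.0707 and 0.217). Arid5a was lost in 6 of 14 alternatives: with the replicate block (0.0567), without leptin ZT2 replicates 2 or 3 (0.334 and 0.774) and without PBS ZT2 replicates 1, 2 or 3 (0.074, 0.132 and 0.103). The quasi-likelihood test called 4. The count was 5, 1 and 1 without leptin ZT2 replicates 1, 2 and 3, and 5 without PBS ZT2 replicate 4. The leptin and JAK-STAT signalling genes had a median of 0.671 (0 of 19 called, 5 adjusted over the list alone; adjusted p = 2.42e-12, and adjusted p = 0.00892 with an estimated correlation). Socs3 was 444.1 ± 332.5 after leptin and 143.7 ± 58 after PBS (1.47 ± 0.805, adjusted p = 1). Interferon response genes had a median of 0.378 (0 of 11 called, 3 adjusted over the list alone; adjusted p = 0.000334, and adjusted p = 0.129 with an estimated correlation). At ZT14 (3 and 3), limma called 0 genes (384 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test; smallest adjusted p = 0.0562), and 3 without PBS ZT14 replicate 1. The leptin list had a median of 0.434 (0 of 19 called, 2 adjusted over the list alone; adjusted p = 3.16e-06, and adjusted p = 0.145 with an estimated correlation). The test of the difference between the times called 0 genes (222 at an unadjusted p under 0.05 in limma, and 0 by the quasi-likelihood test).

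In knockouts at ZT2 (3 and 3), Socs2, a feedback inhibitor of JAK-STAT signalling, rose from 610.8 ± 87.31 to 1661 ± 205.5 (1.45 ± 0.186, adjusted p = 0.000877). The interferon-responsive gene Rtp4 rose by 2.85 ± 0.45 in 3 of 3 libraries (not called without PBS replicate 4, adjusted p = 0.0568). Of the leptin list, 2 of 19 rose (6 adjusted over the list alone; adjusted p = 8.91e-06, and adjusted p = 0.0991 with an estimated correlation). In all, 40 genes rose and 19 fell (quasi-likelihood, 44). The count was 18, 39 and 19 without leptin replicates 1, 2 and 3, and 108, 19 and 6 without PBS replicates 2, 3 and 4.

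In knockouts at ZT14 (3 and 3), Socs2 rose from 472.6 ± 86.75 to 1688 ± 142.3 (1.85 ± 0.186, adjusted p = 1.02e-05) and Rnf122 by 3.04 ± 0.46, the latter lost without leptin replicate 1 (adjusted p = 0.054). Of the leptin list, 2 of 19 rose (5 adjusted over the list alone; adjusted p = 2.12e-09, and adjusted p = 0.0305 with an estimated correlation). In all, 12 genes rose and 0 fell (quasi-likelihood, 11), and 2 were called without leptin ZT14 replicate 1. More genes were called in knockouts than in controls, but the test of the difference between the genotypes called 0 genes at ZT2 (472 at an unadjusted p under 0.05 in limma, and 0 by the quasi-likelihood test) and 0 at ZT14 (371, and 0), where Socs2 had a difference of 1.13 ± 0.263 (adjusted p = 0.999). The count of that test was 1 without control PBS ZT2 replicate 2 and 1 without knockout leptin ZT14 replicate 3.

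The last question was what loss of Arntl in AgRP neurons changes. Arntl itself, measured over the whole gene, differed by -0.84 ± 0.207 between the 12 knockout and the 13 control libraries of the leptin series (adjusted p = 0.143), by -0.94 ± 0.394 in PBS libraries at ZT2 (adjusted p = 0.84) and by -0.23 ± 0.421 at ZT14 (adjusted p = 0.9). This value also covers exons outside the deleted part and does not check the deletion. Hsd11b2, the gene of an enzyme that inactivates glucocorticoids, was higher in PBS knockouts by 10.13 ± 0.79 at ZT2 (adjusted p = 6.41e-08; 2965 ± 338.6 against 2.352 ± 2.671) and by 9.09 ± 0.845 at ZT14 (adjusted p = 2.17e-06), in 3 of 3 libraries each. Hsd11b2 lies 42.7 kb from Agrp (chromosome 8, 105518755 to 105523988), and it was also high, between 1048.4 and 3971.4, in all 17 RiboTag libraries, whose labels name AgRP-Cre but no floxed Arntl. At ZT2, Ifit3 (-4.57 ± 0.706, adjusted p = 0.00845; quasi-likelihood, adjusted p = 0.0758) and Gsta4 (-4.27 ± 0.734, adjusted p = 0.027; quasi-likelihood, adjusted p = 0.227) were lower. Both were lost with a pseudocount of 8 (0.0679 and 0.117), without knockout PBS replicate 4 (0.235 and 0.281) and without control PBS replicates 1 (0.0615 and 0.147) or 4 (0.0694 and 0.08). Gsta4 was also lost without the filter (0.0514), with the replicate block (0.0838) and without knockout PBS replicate 3 (0.0661) or control PBS replicate 3 (0.0659). These genes were named after their values were seen. Astrocyte markers had a median of -2.04 (0 called, 5 lower adjusted over the list alone; adjusted p = 0.000132, and adjusted p = 0.0999 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.0953 (0 of 74 called, 0 adjusted over the list alone; adjusted p = 0.0256, and adjusted p = 0.783 with an estimated correlation) and ribosomal protein genes 0.0771 (0 of 58 called, 0 adjusted over the list alone; adjusted p = 0.0441, and adjusted p = 0.793 with an estimated correlation), and without knockout PBS replicate 4 both sets were lower instead (adjusted p = 0.032 and 0.000564). The 3 calls at ZT2 became 34, 1, 1, 11 and 1 without knockout PBS replicates 2 and 4 and control PBS replicates 1, 2 and 4. The 1 call at ZT14 became 2, 2 and 2 without knockout PBS replicates 1, 2 and 3, and 6 without control PBS replicate 1.

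All leptin-series libraries were pooled for genotype after the first results were seen, with time and treatment in the model (12 knockouts, 13 controls). Nr1d2 (-2.49 ± 0.341, adjusted p = 0.000634) and Per3 (-1.62 ± 0.291, adjusted p = 0.017, and 0.0536 without control leptin ZT2 replicate 1) were lower in knockouts. Hsd11b2 (10.09 ± 0.416), Fstl5 (1.22 ± 0.158) and the phosphodiesterase gene Pde5a (1.76 ± 0.258) were higher, and Ifit3 (-2.74 ± 0.371) was lower. Nr1d1 had a difference of -0.73 ± 0.158 (adjusted p = 0.0629). Of 18 core clock genes, 2 were lower (3 higher and 5 lower adjusted over the list alone). In camera the set had adjusted p = 0.0797. Fry's test for change in either direction, given only here, had an unadjusted p = 2.43e-12 (n = 12 and 13), which a few genes can carry. Agrp (0.19) and Npy (0.17) did not pass. In all, 4 genes were higher and 7 lower (quasi-likelihood, 10). The count was 37 and 19 without knockout PBS ZT14 replicates 1 and 3, and 19 without knockout PBS ZT2 replicate 2.

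Time of day was also tested within each genotype after PBS. In controls (3 at ZT14, 4 at ZT2), 1 gene was called, Stac, named after its values were seen (-5.24 ± 0.774, adjusted p = 0.00842; 0.814 ± 1.41 against 64.25 ± 42.85; quasi-likelihood, adjusted p = 0.262). Stac was also lost with a pseudocount of 8 (0.229), with the replicate block (0.0947) and without control PBS ZT14 replicates 1 or 3 (0.0755 and 0.0834) or ZT2 replicate 4 (0.0708). Nr1d1 was 458 ± 109.7 at ZT14 and 182 ± 84.84 at ZT2 (1.40 ± 0.301, adjusted p = 0.243), and core clock genes had a median of 0.718 (5 higher and 2 lower adjusted over the list alone; adjusted p = 0.000143, and adjusted p = 0.0772 with an estimated correlation). The count was 0, 2 and 0 without control PBS ZT14 replicates 1, 2 and 3, and 10 and 0 without control PBS ZT2 replicates 2 and 4. In knockouts (3 and 3), limma called 0 genes (692 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test), 31 without ZT2 replicate 2 and 1 without ZT14 replicate 1. Nr1d1 had a difference of 0.61 (adjusted p = 1). The test of the difference between the genotypes called 0 genes in limma (580 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test), and 1 without control PBS ZT14 replicate 3.

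**Figure D4:**
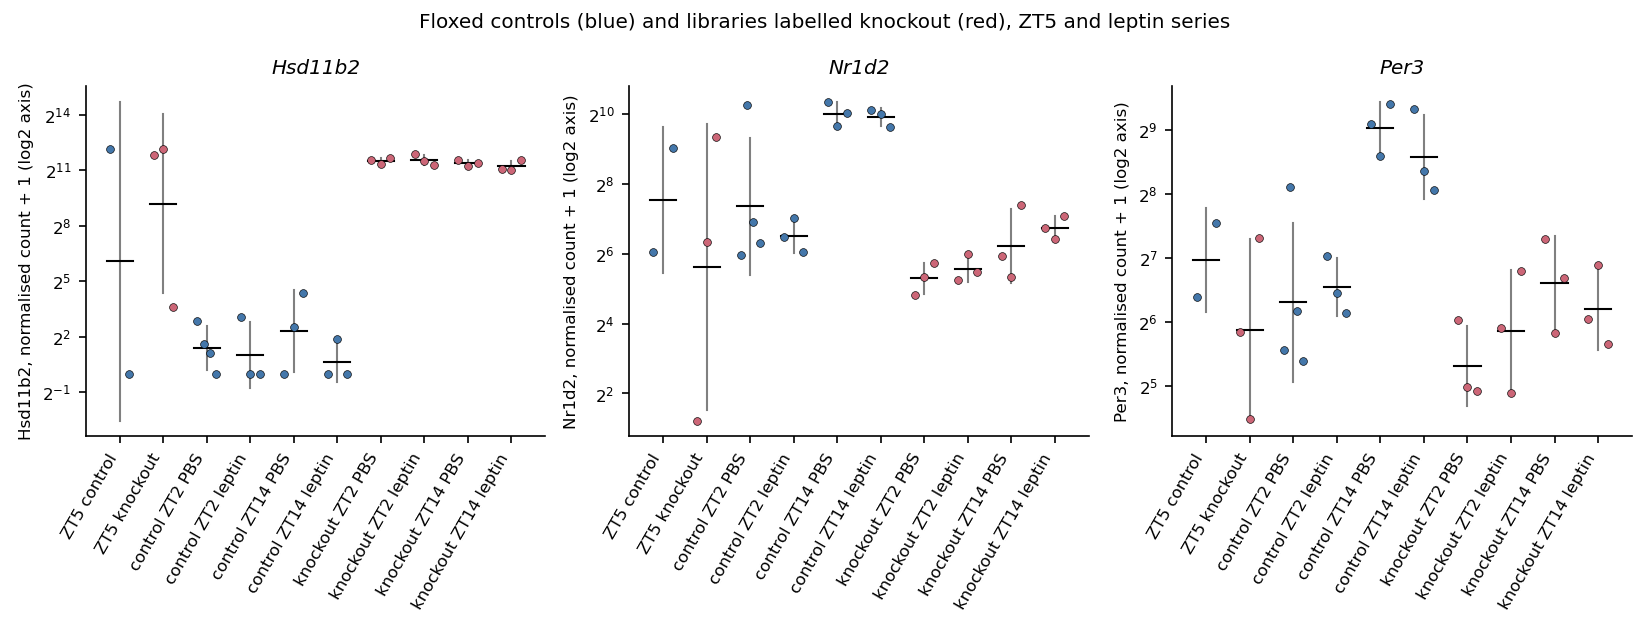
Hsd11b2, Nr1d2 and Per3 in floxed controls and in libraries labelled knockout, in the ZT5 and leptin series (points; black line, mean; grey bar, 1 SD either side, on the log2 scale). In the leptin series Hsd11b2 lay between 0 and 19.743 in controls and between 2091.6 and 3749.1 in knockouts.

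At ZT5 (3 knockouts, 2 controls), Arntl was 500.6 ± 36.09 in knockouts and 570.4 ± 254.5 in controls (-0.12 ± 0.311, adjusted p = 0.932), again over the whole gene. Limma called 0 genes (1157 at an unadjusted p under 0.05, and 0 by the quasi-likelihood test; smallest adjusted p = 0.428). Agrp was 124100 ± 57370 in knockouts and 90450 ± 1462 in controls (0.34 ± 0.354, adjusted p = 0.788), and Lepr 476.3 ± 336.1 and 190.2 ± 8.076 (1.08 ± 0.525, adjusted p = 0.587). Glucocorticoid response genes had a median of 1.06 (0 of 12 called, 2 adjusted over the list alone; adjusted p = 0.000268, and adjusted p = 0.845 with an estimated correlation) and a ZT5 minus PBS median of -1.26. Hsd11b2, singled out after its values were seen, was 4628.3 in the library labelled control 1 and 0 in control 2, and 3588, 4572.7 and 11.243 in the libraries labelled knockout 1, 2 and 3. No library was moved to another group. Without the library labelled control 1, 98 genes were called, 97 of them higher, with a single control library left that is taken to vary like the others.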

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

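The tests of the first 3 patterns below, with that of an exchange of libraries set before its values were computed, and the list tests on refed against ad libitum cells were chosen after the results were seen, while Dixon's test and the list tests on other differences between effects were planned.

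The 25 fasted and 5 ZT5 libraries shared a profile that the other 50 lacked, and a library or sequencing batch, food deprivation, or a bias by GC content and length could each lie behind it. Of the genes called in fasted cells and back after refeeding, 91.7% at ZT2 and 93.3% at ZT14 lay on the side of the fasting call in ZT5 minus PBS controls (89.1% and 90.7% with ZT5 control 2 alone), which goes with a batch but only restates the shared profile, and food deprivation of the ZT5 mice would give the same. Genes called alike in fasted and refed cells had medians of 0.063 at ZT2 and -1.14 at ZT14 there (0.0704 and -0.855 with control 2 alone), which goes against that batch for these, but 98.3% of those called at ZT2 also lay on the side of the fasting call in PBS controls minus ad libitum libraries not used for the calls, so something other than feeding may set the ad libitum libraries apart, unless the PBS mice were deprived of food, and in RiboTag fasting 73.1% (ZT2) and 85.2% (ZT14) lay on that side, so that an effect of feeding stays open too. The share of these genes on the side of the fasting call in ZT5 minus PBS controls was 52.8% at ZT2, and 20.8% of the 53 higher ones at ZT14 (median -1.15 against 3.28 with fasting), which would go against food deprivation behind the ZT5 libraries if the genes marked it, and since they may mark the ad libitum libraries instead, it cannot be told apart from its absence. After the GC and length correction 5279 genes were called at ZT2 against 5593 before, with 3762 called both times, which goes against that bias behind the count as a whole but not for each gene.

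Hsd11b2 was high with Cre and low without, except in 2 of the 5 ZT5 libraries, and loss of Arntl, the Cre allele near Agrp, or an exchange of libraries could lie behind it. The lowest RiboTag value was 1048.4 with no floxed Arntl on the label, which goes against loss of Arntl. Of 29 libraries with Cre outside the ZT5 series, 29 lay above 500, which goes with the Cre allele, whose gene lies 42.7 kb away. With control 1 and knockout 3 exchanged, the gap in correlation with the genotype difference of the PBS libraries was 0.162 (0.0328 as labelled), reached by 1 of 10 splits, the exchange itself, and 10 splits are too few for a share under 0.05. Arntl runs with the labels for control 1, highest of the 5 (750.34; control 2, 390.39; knockouts, 540.48, 470.24 and 490.96), so the exchange stays open, and the ZT5 result rests on it.

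Genes called between ZT14 and ZT2 in fasted NPY-GFP cells could come from a set of fasted libraries with low Lars2 at both times, or from RNA of other cells. With the set (7 libraries against 8) as a term, 42 of 42 were called, but a set at both times cannot decide this. Without the 3 libraries with Gfap above 500, 34 were called (30 also without ad libitum ZT2 replicate 4), but 21 of the 34 were among the 42, and without 1 of them, fasted ZT2 replicate 6, 25 were called, so RNA of other cells stays open. Leaving out single libraries with lower Gfap gave counts as low (18 without fasted ZT2 replicate 3).

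Single values stood apart from their group by Dixon's test in 9 of 98 cases, and chance flags about 1 in 20. In ad libitum NPY-GFP cells at ZT2, Arntl was 395 in replicate 2 (489 next). In fasted cells at ZT14, Arntl was 83.5 in replicate 3 (182 next) and Per2 was 1130 in replicate 5 (393 next). In control PBS libraries at ZT2, Per1 was 592 in replicate 2 (126 next). In refed cells at ZT14, Socs3 was 32 in replicate 2 (152 next) and Hsd11b2 was 5.64 in replicate 4 (0 in the others), which says nothing, since with the others at 0 any value gives the highest ratio. In refed cells at ZT2, replicate 4 had Socs3 at 6.88 (53.8 next), Nr1d1 at 525 (144 next) and Dbp at 11 (51.4 next).

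Gene lists also passed in the tests of a difference between effects, where limma called 0 genes in each, and none of these calls held with an estimated correlation. The fasting effect differed between the times in sorted cells for ER folding (adjusted p = 0.000153, and adjusted p = 0.328 with an estimated correlation), cholesterol synthesis (0.000167, 0.328), secretory pathway (0.0039, 0.821), core clock (0.0166, 0.328), other hypothalamic markers (0.0166, 0.328) and heat shock (0.0224, 0.632). In RiboTag it did for ribosomal proteins (3.4e-28), oxidative phosphorylation (1.49e-18), GABA receptors (0.0133) and secretory pathway (0.03), each adjusted p = 0.866 with an estimated correlation. For refed against ad libitum cells these were secretory pathway (2.04e-12, 0.137), cholesterol synthesis (6.05e-09, 0.137), ER folding (7.45e-08, 0.137), oxidative phosphorylation (0.0107, 0.854), autophagy (0.0199, 0.137) and core clock (0.0396, 0.241). The leptin effect in controls differed between the times for oxidative phosphorylation (3.15e-05, 0.945), interferon response (0.00368, 0.331), immediate early genes (0.0226, 0.807) and ribosomal proteins (0.0237, 0.945). Between the genotypes it differed at ZT2 for ER folding (0.000772, 0.753). At ZT14 it did for secretory pathway (0.00014, 0.265), oxidative phosphorylation (0.00014, 0.778), astrocyte markers (0.000208, 0.114), glutamate receptors (0.00209, 0.218), POMC markers (0.00371, 0.114), tanycyte markers (0.00804, 0.218), potassium channels (0.0183, 0.227), ribosomal proteins (0.0183, also lost) and other hypothalamic markers (0.0293, 0.218). The effect of time differed between the genotypes for oxidative phosphorylation (7.87e-05, 0.856), glucocorticoid response (0.00164, 0.634), interferon response (0.00288, 0.584), ribosomal proteins (0.00933, 0.856) and secretory pathway (0.0119, 0.856).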

How the results depend on the processing

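Of 2100 values of named genes, 584 were calls. Calls lost and gained were 8 and 1 after rescaling, 11 and 6 with pseudocount 8, and 57 and 1 without the filter. By the quasi-likelihood test it was 74 and 22, with the replicate block 51 and 6, and with library weights 8 and 153. With the GC and length correction it was 81 and 18 (9 reversed), without doubted libraries 53 and 6 (of 547). Leaving out single libraries gave 762 and 70 (of 6485, 0 reversed). Of 173 list calls, 2 held with an estimated correlation. Besides those listed at the start, splitting ad libitum libraries and leaving out fasted ones with Gfap above 500 were chosen after seeing the data. Rescaling and leaving out doubted libraries moved no count by more than 1.5 times. The cause was not tested for any change below, except where fewer libraries are the change itself. A fit of only the groups compared equals the full fit for the ZT5 comparison, the RiboTag difference between times and genotype over the leptin series, and no leptin library was doubted, so these were not run. Depth limits low genes most, with 5.93 M reads in the lowest library.

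Pseudocount 8: leptin in controls at ZT14 1, genotype in PBS libraries at ZT2 1, time in PBS controls 0, genotype over the leptin series 21. No filter: time in ad libitum cells 3, fasted cells 26, refed cells 2; leptin in controls at ZT2 7; genotype in PBS libraries at ZT14 3; time in PBS knockouts 2. Library weights, sorted cells: fasting at ZT14 5539, its difference between times 22, refeeding at ZT14 3960, refed against ad libitum at ZT14 737, its difference 101, time 35 (ad libitum), 301 (fasted) and 93 (refed), where the fasted lists reversed for oxidative phosphorylation (adjusted p = 0.0039, higher; lower at 0.000379) and for cytosolic ribosomal proteins (adjusted p = 0.000197, higher; lower at 0.00249). Library weights, RiboTag: fasting 2877 at ZT2 and 2145 at ZT14, time in fasted 1. Library weights, leptin series: leptin in controls 73 at ZT2 and 165 at ZT14, their difference 4, leptin in knockouts at ZT2 620, its difference between genotypes 68, genotype in PBS at ZT2 240, time 6 (controls) and 8 (knockouts), genotype over all 387. Library weights, overlaps: sorted and RiboTag 1637 at ZT2 and 1225 at ZT14, fasting and refeeding at ZT14 3046, fasted and refed at ZT14 608.

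Replicate block: ZT5 2, time in fasted cells 9, leptin in controls at ZT14 2, time in PBS controls 0. Libraries of the same number had median correlations of -0.0216 (ZT5), 0.00123 (sorted), -0.032 (RiboTag) and 0.0321 (leptin series). Above 0.1 lay 0 of 2, 12 of 65, 7 of 22 and 22 of 78 pairs, so pairing of some samples stays open. Quasi-likelihood: time in fasted cells 26, refed cells 0, PBS controls 0, genotype in PBS at ZT2 1. GC and length correction: refed against ad libitum at ZT14 105, time in fasted cells 75, leptin in controls 7 at ZT2 and 2 at ZT14, genotype in PBS at ZT14 3, genotype over all 36, fasted and refed at ZT14 98. It reversed Hspa4l (0.59), Grin2b (0.20) and Gabrg3 (0.21) with fasting at ZT2, Kcnma1 (-0.0663), Cyc1 (0.42), Gria2 (-0.23) and Gabrg3 (-0.0129) with refeeding at ZT2, and Gabrb1 (-0.36) and Grin2b (-0.0802) with refeeding at ZT14. Only the groups compared: fasting difference between times in sorted cells 1, refed against ad libitum at ZT14 362, time in fasted cells 10 and refed 0, RiboTag fasting at ZT2 386, leptin 1 in controls at ZT2 and 6 in knockouts at ZT14, genotype in PBS 1 at ZT2 and 3 at ZT14, time in PBS controls 0. With fasted libraries split, fasting and refeeding shared 1232 and 1461 at ZT2 and 834 and 782 at ZT14; with ad libitum libraries split, fasted and refed shared 577 and 680 at ZT2. With the low-Lars2 term, time in fasted cells gave 72. ZT5 control 2 alone moved 4 of the 6 shares given in the report by more than their 95% interval.

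Leaving out single libraries, lowest to highest: ZT5 0 to 98. Sorted cells: fasting 5025 to 5570 at ZT2, 1244 to 3502 at ZT14, difference 0 to 0; refeeding 2559 to 3536 and 1138 to 2447; refed against ad libitum 1439 to 2832 and 21 to 45, difference 0 to 2; time 0 to 0 (ad libitum), 18 to 67 (fasted) and 0 to 43 (refed). RiboTag: fasting 439 to 2252 at ZT2 and 556 to 893 at ZT14, difference 0 to 0; time 0 to 1 (ad libitum) and 0 to 3 (fasted). Overlaps: sorted and RiboTag 341 to 1219 at ZT2 and 339 to 472 at ZT14; fasting and refeeding 1876 to 2332 and 820 to 1873; fasted and refed 1059 to 1697 and 20 to 54. Leptin: controls 1 to 5 at ZT2, 0 to 3 at ZT14, difference 0 to 0; knockouts 6 to 108 and 2 to 10; difference between genotypes 0 to 1 at ZT2 and 0 to 1 at ZT14. Genotype: PBS 1 to 34 at ZT2 and 1 to 6 at ZT14, all 8 to 37. Time in PBS: 0 to 10 (controls), 0 to 31 (knockouts), difference 0 to 1. Without knockout PBS ZT2 replicate 4, the genotype lists of oxidative phosphorylation and ribosomal proteins at ZT2 reversed, as given above. Their adjusted p over libraries left out ran from 2.75e-08 to 0.338 and 5.93e-08 to 0.355.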

Other observations

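Further gene groups moved as sets without passing with an estimated correlation. After leptin in knockouts, POMC neuron markers had a median of 1.2 at ZT2 (0 of 4 called, 3 adjusted over the list alone; adjusted p = 0.00467, and adjusted p = 0.0991 with an estimated correlation) and 1.27 at ZT14 (0 of 4 called, 1 adjusted over the list alone; adjusted p = 0.00136, and adjusted p = 0.0623 with an estimated correlation). Pomc was 1325 ± 482.7 after leptin and 310.4 ± 126.6 after PBS at ZT14 (2.11 ± 0.488, adjusted p = 0.156). Interferon response genes had a median of 0.505 after leptin in knockouts at ZT2 (1 of 11 called, 2 adjusted over the list alone; adjusted p = 0.0049, and adjusted p = 0.266 with an estimated correlation), and Rtp4 rose from 75.68 ± 24.81 to 541.8 ± 154.1. In PBS libraries at ZT2 interferon response genes had a median of -0.676 in knockouts against controls (1 of 11 lower, 3 adjusted over the list alone; adjusted p = 0.000503, and adjusted p = 0.144 with an estimated correlation).

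In refed NPY-GFP cells secretory pathway genes had a median of -0.35 at ZT14 against ZT2 (0 of 37 called, 0 adjusted over the list alone; adjusted p = 2.05e-10, and adjusted p = 0.27 with an estimated correlation). In fasted RiboTag libraries nuclear genes of oxidative phosphorylation had a median of -1.79 between the times (0 of 74 called, 0 adjusted over the list alone; adjusted p = 2.38e-29, and adjusted p = 0.587 with an estimated correlation).

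The splits of the planned comparisons were set before the results were seen, and those of the 4 added comparisons after. In each, libraries were exchanged between the compared groups, and the number of splits calling at least as many genes includes the real one. For fasting in sorted cells it was 1 of 100 at ZT2 (5593 called, highest other 438) and 3 of 100 at ZT14 (2758, highest other 2905). Refeeding gave 1 of 100 at ZT2 (3262, highest other 2805) and 1 of 100 at ZT14 (1741, highest other 1732). Refed against ad libitum cells gave 1 of 100 at ZT2 (2648, highest other 1299) and 1 of 35 at ZT14 (56, highest other 1). Fasting in RiboTag gave 1 of 100 at ZT14 (817, highest other 446) and 3 of 56 at ZT2 (1219, highest other 2234), so that at ZT2 other splits reached the count in a share of at least 0.05. Leptin in controls at ZT2 gave 1 of 35 (3, highest other 1), and genotype over the leptin series 3 of 100 (11, highest other 230). For time of day, fasted NPY-GFP cells gave 7 of 100 (42, highest other 3305) and refed cells 4 of 100 (4, highest other 85). Genotype in PBS libraries at ZT2 gave 3 of 35 (3, highest other 87) and time in PBS controls 4 of 35 (1, highest other 11). For 10 splits a share under 0.05 is out of reach, and the real count and the highest other were 59 and 0 for leptin in knockouts at ZT2, 12 and 4 at ZT14, and 1 and 1 for genotype in PBS libraries at ZT14 (2 of 10 splits).

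Where limma called 0 genes, every split called as many. The highest other count was 37 for time in ad libitum NPY-GFP cells (84 of 84 splits), 3 and 3246 for time in ad libitum (35 of 35) and fasted RiboTag libraries (100 of 100), 0 for leptin in controls at ZT14 (10 of 10) and 13 for time in PBS knockouts (10 of 10). For the tests of a difference between effects (100 of 100 splits each) it was 1 for fasting in sorted cells, 14 for refed against ad libitum cells, 2 for fasting in RiboTag, 1628 for leptin in controls between the times, 4 and 135 for leptin between the genotypes at ZT2 and ZT14, and 36 for time between the genotypes. Some splits called far more genes than the real one, as for time in fasted NPY-GFP cells (3305 against 42), and a structure of the samples other than the groups may lie behind this. The split with 3305 calls set all 7 low-Lars2 libraries and fasted ZT2 replicate 6 apart, and why was not tested.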
